A study of Mus musculus with 2 samples.

How the data were processed

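The data were 2 droplet single-cell RNA libraries of sorted CD45-negative, Ter119-negative, CD31-negative, DAPI-negative, tdTomato-positive cells from knee cartilage of Procr-CreER;tdTomato mice, 1 library per group (pulse and trace) with 3 mice pooled in each. Per the labels the tissue was digested with collagenase, Dispase and DNase, the libraries were made with the 10x Genomics 3' V2 kit and read on a NovaSeq instrument. The labelled protocol also speaks of periosteum cells, and its treatment and batch fields hold library terms rather than a treatment or a batch, so neither was used. The authors deposited raw UMI counts per gene and barcode with no normalization, and only called barcodes, the lowest with 500 UMIs. Per the file headers the count matrices came from Cell Ranger 7.1.0, whereas the submitters' notes name Cell Ranger 3.0.1 with mm10, and this disagreement could not be settled. The notes also name STAR, HTSeq, Seurat and DESeq2 without saying what each made, and the matrices hold whole counts. Whether intron reads were counted and which annotation release was used are not given in the sources used here. Of 32286 features, including an added Tdtomato transgene, 32158 (99.6%) matched a GENCODE M21 entry.

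Cells with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes passed, which left out 330 pulse and 1176 trace barcodes. Scrublet, run through scanpy 1.11.5 on each library, marked only 4 of 6533 pulse cells (0.0612%) and 224 of 9247 trace cells (2.42%) at its own threshold. After this was seen, the highest-scoring 5% of each library were removed instead, 327 and 462 cells. Kept cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components and a graph of 20 nearest neighbours were used for joint Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9), without integration, which gave 13 clusters. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

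A cluster took the name of a cell class from 18 marker lists. Markers counted as raised at 1.5-fold or more over the mean of the other clusters and at 20 CPM or more. Among classes with 2 or more raised markers, the class with the highest mean log2 fold was the candidate, and its name stood if 3 or more of its markers were raised and no other class had more markers among the cluster's 10 leading genes by fold over all other cells. The lists were fixed before the data were examined, as were the cell filter, the comparisons, the 21 gene lists, the floors and the rule for named genes. The details of the naming check were set after the clusters were seen. The versions looked at were a clustering with Scrublet's own doublet threshold, merging of clusters by correlation, leading genes by fold over the mean of the other clusters or over all other cells, with and without genes that the rule for named genes leaves out, and candidates with at least 2 or at least 3 raised markers. The version used was chosen knowing that the superficial-zone clusters of both libraries pass under it, and the others are given as alternatives. Names end in "-like" because they rest on markers alone.

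With 1 library per group no test across samples was possible. For each cell class, raw UMIs were summed per library and scaled to the total UMIs of the summed cells (CPM), and the ratio of trace over pulse was given with an exact conditional Poisson 95% interval. Genes at 20 CPM or more in at least 1 library were counted as higher or lower at 2-fold. A gene with 0 UMIs in a library was set against a floor of 3 UMIs over the group. Shares of cells carry exact Clopper-Pearson 95% intervals. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs, which left 4477 pulse and 6828 trace cells over all classes. A cell counted as carrying cycle transcripts with 2 or more UMIs of the S and G2/M lists joined. List medians were set against 10000 random lists of the same size and matched mean expression, a description of these libraries and not a test across animals. A list with fewer than 3 measured members got no median.

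Genes named were Procr, Prg4 and Acan, the 15 highest and 15 lowest ratios over both chondrocyte-like classes among genes at 100 CPM or more in at least 1 library, and the 5 highest and 5 lowest over all kept cells. To these came up to 4 members per list with the largest absolute log2 ratio, and the sex-linked genes. Predicted gene models and mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes were left out of naming, except haemoglobin genes within the erythroid list. Marker genes that led a cluster, Gm42418, Fos and genes from other single cell classes were named after their values were seen.

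The steps were tested on simulated counts drawn from the summed profile of the chondrocyte-like cells, with 200 of 5908 genes altered. None of 67 genes altered 1.5-fold, all 67 altered 2.5-fold and 65 of 66 altered 4-fold were counted as past 2-fold, and no unaltered gene was. The intervals held the simulated truth for 95.1% of genes. The simulated counts were Poisson draws without variation between mice, libraries or cells. They therefore check the computation and give no error rate for comparing 1 library with 1 other. Alternatives covered the cell filter, doublets, resolution, variable genes, separate clustering, scaling, weighting of cells and zones, floors, a pseudocount, thinning and the naming check. The planned weighting of the clusters of a class alike was not run, because clusters 1 and 2 of the superficial-zone-like class held 19 trace and 24 pulse cells, and the zones were weighted alike instead.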

Results

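Single-cell RNA sequencing was done on 2 libraries of tdTomato-positive cells sorted from the superficial layer of mouse knee articular cartilage. In Procr-CreER;tdTomato mice, tamoxifen switches on a red reporter in cells that express Procr, the gene of the protein C receptor, and their descendants keep the label. Tamoxifen was given at 4 weeks of age, and cells were taken 2 days later for the pulse library and 4 weeks later for the trace library. Each library pooled 3 mice, and the barcodes do not say which mouse a cell came from. Each group had 1 library, so no value has a replicate error, and no difference between the libraries was tested across animals. The pulse library held 6863 barcodes and 23306063 unique molecular identifiers (UMIs), and the trace library held 10423 barcodes and 40284041 UMIs. After filtering, 6206 pulse cells with a median of 2791 UMIs and 8785 trace cells with a median of 3581 UMIs were kept. Intervals are exact 95% intervals, Poisson for sums and Clopper-Pearson binomial for shares, and cover counting error only.

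The libraries differed in sex-linked genes and in the share of ribosomal RNA-associated transcripts as well as in chase time. Xist, the RNA that silences an X chromosome in female cells, had 3 UMIs in kept pulse cells and 13131 in kept trace cells, or 0.140 and 361 CPM, the UMI count scaled to the total of the summed cells. The Y-linked genes went the other way, with 3970 pulse and 10 trace UMIs for Ddx3y and 3665 and 1 for Uty. Eif2s3y had 1011 pulse UMIs and none in trace, and Kdm5d had 572 and none. A count of 0 in the 8785 trace cells allows up to 0.101 CPM for each of these genes. Chase time, age at collection and the sex shown by these genes therefore went together, and no comparison below separates them. Gm42418, a transcript that overlaps ribosomal RNA, took 0.664% of pulse UMIs and 6.92% of trace UMIs. Together with AY036118, Cmss1, Gphn, Camk1d and Lars2, it took 0.976% and 9.15%.

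The comparison of cell classes asks which classes the sorted cells fell into shortly after labelling and after the chase. A share of kept cells is not a share of labelled cells, since some classes held few reporter transcripts. Cells that resembled superficial-zone articular chondrocytes made up 63.8% (62.6% to 65.0%) of kept pulse cells and 51.4% (50.3% to 52.4%) of kept trace cells. Cells like deeper-zone chondrocytes, which carried the cartilage matrix genes Matn3, Col9a1 and Epyc, were 13.4% (12.6% to 14.3%) of pulse and 3.12% (2.77% to 3.50%) of trace. Within both chondrocyte-like classes together, the deeper-zone-like share was 17.4% (16.3% to 18.5%) in pulse and 5.73% (5.08% to 6.42%) in trace. Synovial lining fibroblast-like cells, with Clic5 and Col22a1, were 6.19% (5.60% to 6.82%) and 12.9% (12.2% to 13.6%), and loose connective tissue fibroblast-like cells, with Clec3b and Pi16, were 2.59% (2.21% to 3.02%) and 8.33% (7.76% to 8.93%).

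Osteoblast-like cells, with the bone matrix genes Bglap and Dmp1, were 1.08% (0.838% to 1.37%) of pulse and 3.86% (3.47% to 4.28%) of trace. In trace they held 0.0413 UMIs of the reporter transcript per cell (0.0226 to 0.0693), against 0.0367 (0.0168 to 0.0697) in neutrophil-like cells. Their label was therefore not told from background, and their share is not read as labelled cells. Mural-like cells, with Notch3 and Myh11, were 0.580% (0.407% to 0.802%) and 3.32% (2.96% to 3.72%). The sort excluded cells with CD31, CD45 or Ter119, surface proteins of endothelial cells, leukocytes and red cells. Endothelial-like cells, with Emcn and Cdh5, were still 0.902% (0.682% to 1.17%) of pulse and 3.98% (3.59% to 4.41%) of trace. Neutrophil-like cells, with S100a8 and S100a9, were 4 pulse cells (0.0645%) and 245 trace cells (2.79%). A lymphocyte-like cluster, whose leading genes also included Car1 of red cell precursors and Pf4 of platelets, held 4 pulse cells and 392 trace cells (4.46%). A cluster of 703 pulse cells (11.3%) and 519 trace cells (5.91%), led by Npy, Angptl7 and Ltbp2, met no class and stayed unnamed (cluster 5).

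**Figure D1:**
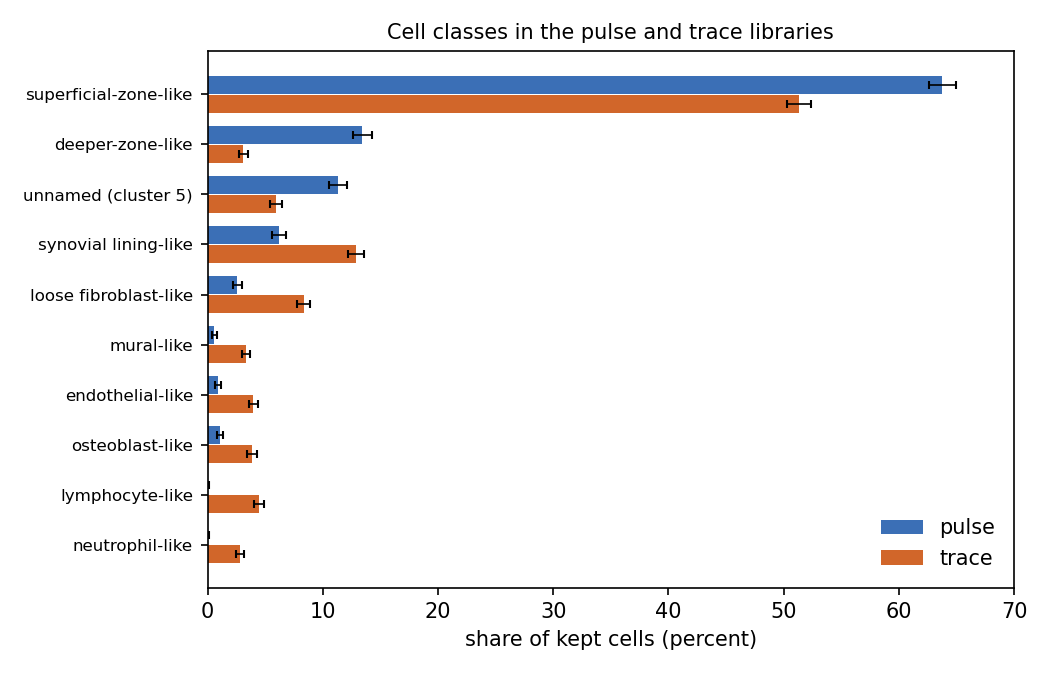
Share of kept cells (percent, horizontal axis) in each cell class (vertical axis) for the pulse and trace libraries, with 1 library each and bars for the exact 95% binomial interval. The superficial-zone-like share was 63.8% in pulse and 51.4% in trace, and the deeper-zone-like share was 13.4% and 3.12%.

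The superficial-zone-like class joined 4 clusters in which the libraries were unevenly mixed. Cluster 1 held 3764 pulse and 19 trace cells, cluster 2 held 24 and 2762, cluster 3 held 145 and 1581, and cluster 13, led by heat shock genes, held 25 and 150. Cluster 1 had Prg4 at 8812 CPM, below cluster 2 at 29447 CPM and cluster 3 at 20312 CPM. None of the 10 leading genes of clusters 1, 3 and 13 was a superficial-zone marker, and 2 of those of cluster 2 were. When the name of cluster 1 was checked on fold over the mean of the other clusters, Col10a1 came among its leading genes. It then stayed unnamed, which left 3.13% of pulse cells in the class. That share was 36.1% in pulse and 40.2% in trace with at least 1000 genes per cell, and 46.7% and 26.8% when each library was clustered on its own, so the order of the libraries depended on the processing. Values for the class below compare these clusters, and whether cluster 1 is the same zone as clusters 2 and 3 was not settled.

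The gene comparison asks how the labelled chondrocyte-like cells differed between pulse and trace. In superficial-zone-like cells, Prg4, which encodes the joint lubricant lubricin, was 3.13-fold higher in trace (3.11 to 3.15), at 8726 CPM in pulse and 27271 in trace. Sparc, which encodes a collagen-binding matrix protein, was 9.45-fold lower in trace (9.38 to 9.52), at 40323 and 4267 CPM. Cytl1, a secreted protein gene of cartilage, was 3.31-fold higher (3.28 to 3.35), and Acan, the gene of the main cartilage proteoglycan, was 1.26-fold higher (1.25 to 1.28). Of the cartilage collagen genes, Col2a1 stood at 0.525 of the pulse level (0.519 to 0.531). Col9a1 was 7.70-fold lower in trace (6.42 to 9.28), and Col11a2 stood at 0.337 of the pulse level (0.323 to 0.352). Col2a1 was also lower in synovial lining-like cells (182 CPM in pulse, 20.0 in trace) and loose connective tissue fibroblast-like cells (260 and 21.0 CPM). Col11a2 was at least 2-fold lower in both of those classes too. Free cartilage RNA in the pulse droplets was therefore not excluded as part of these collagen ratios. Sox9, the chondrocyte transcription factor gene, stood at 0.490 (0.483 to 0.497), and Bmp2 at 0.361 (0.356 to 0.366).

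In deeper-zone-like cells, which were 833 in pulse and 274 in trace, Prg4 stood at 90.9 CPM in pulse and 310 CPM in trace. Endothelial-like cells had 79.2 and 377 CPM and mural-like cells 80.0 and 333 CPM, so the ratio of 3.41 (3.01 to 3.86) was not told from free RNA. Sparc did not differ there beyond counting error, with a ratio of 0.990 (0.976 to 1.00). Cytl1 was 13.9-fold higher (12.5 to 15.6), and Acan stood at 0.759 of the pulse level (0.732 to 0.788). Matn3 and Col9a1, both matrix genes of growing cartilage, stood at 0.345 (0.321 to 0.370) and 0.398 (0.381 to 0.416). Ibsp, the bone sialoprotein gene, was 30.0-fold higher (27.0 to 33.4) in this class and stood at 0.332 (0.315 to 0.350) in superficial-zone-like cells. Of 4 osteoblast markers measured in deeper-zone-like cells, 2 (Ibsp, and Bglap at 3.70-fold) were at least 2-fold higher and none lower, with a median log2 ratio of 1.16, at percentile 99.93 of random lists. Col1a1, the type I collagen gene, was 10.1-fold higher there (8.68 to 11.9), at 39.1 CPM in pulse and 396 CPM in trace. Markers of other cells were higher in these 274 trace cells too, with the neutrophil genes S100a8 at 0.349 and 39.2 CPM and S100a9 at 0.698 and 88.5 CPM, the mural gene Tagln 8.40-fold higher (5.85 to 12.3) and the synovial lining marker Hbegf 2.21-fold higher (1.96 to 2.49).

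Over both chondrocyte-like classes together, which held 4791 pulse and 4786 trace cells with 18175040 and 21835072 UMIs, 6372 genes reached 20 CPM in at least 1 library. Of these, 107 were at least 2-fold higher in trace and 630 at least 2-fold lower, and the median log2 ratio was -0.25. Scaling by the median ratio, which sets that shift to 0, gave 218 higher and 418 lower. With at least 1000 genes per cell the counts were 189 and 898. With naming by fold over the mean, which left cluster 1 out, they were 517 and 1389. The class sums mix the zones in different shares, so a ratio over the sum differs from those within the zones. Prg4 was 4.22-fold higher over the sum (4.19 to 4.25), Acan 1.25-fold (1.23 to 1.26) and Procr 1.90-fold (1.48 to 2.45). The log2 ratio of Acan was -0.25 when each library was clustered on its own. That of Prg4 ran from 1.64 with the zones weighted alike to 6.22 with naming by fold over the mean. Among 5602 genes measured in both classes, 45 were at least 2-fold higher in both, where independence would give 4.22. Another 186 were at least 2-fold lower in both, where independence would give 48.0, and 12 went opposite ways. Both comparisons used the same 2 libraries, so any difference between the libraries as a whole adds to these overlaps, and the excess over independence is not read as a shared effect.

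The 15 genes with the highest ratios over the sum opened with Xist (3464-fold, 959 to 28604, from 2 pulse UMIs). Next came Msmp, a secreted microseminoprotein gene, at 22.9-fold (20.5 to 25.7), with 17.9 CPM in pulse and 409 in trace. Cmss1 at 12.7-fold, Lars2 at 9.70-fold, Gphn at 6.77-fold, Camk1d at 4.51-fold and AY036118 at 3.21-fold belong to the ribosomal RNA-associated transcripts above. Col1a1 was 4.95-fold higher (4.45 to 5.50), C4b and Cd14, genes of complement and innate immunity, were 3.65-fold and 4.27-fold higher, and Cytl1 was 4.47-fold higher. Cdk8 was 5.42-fold, Jarid2 3.62-fold and Tmtc2 3.54-fold higher, and Prg4 completed the 15.

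The 15 genes with the lowest ratios over the sum held the Y-linked Uty and Ddx3y and the histone gene Hist1h4i at 0.0348 of the pulse level. Matn3 stood at 0.0846, Col9a1 at 0.0941 and Col11a2 at 0.146, and Fxyd2 at 0.108. Sparc stood at 0.156 over the sum. The metallothionein gene Mt1, which binds metal ions, stood at 0.104, and it was 2.78-fold lower in superficial-zone-like cells and at 0.0817 of the pulse level in deeper-zone-like cells. Ulk4 and Daglb stood at 0.0943 and 0.101. Several of the 15 were not lower in superficial-zone-like cells alone. Cdkn1c, a cell cycle inhibitor gene, stood at 0.0911 over the sum and 1.19 (0.886 to 1.60) in that class. Scd2, a fatty acid desaturase gene, stood at 0.102 and 1.06 (0.904 to 1.25), Scd1 at 0.145 and 0.873 (0.708 to 1.08), and Ppa1 at 0.161 and 1.32 (1.18 to 1.48).

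**Figure D2:**
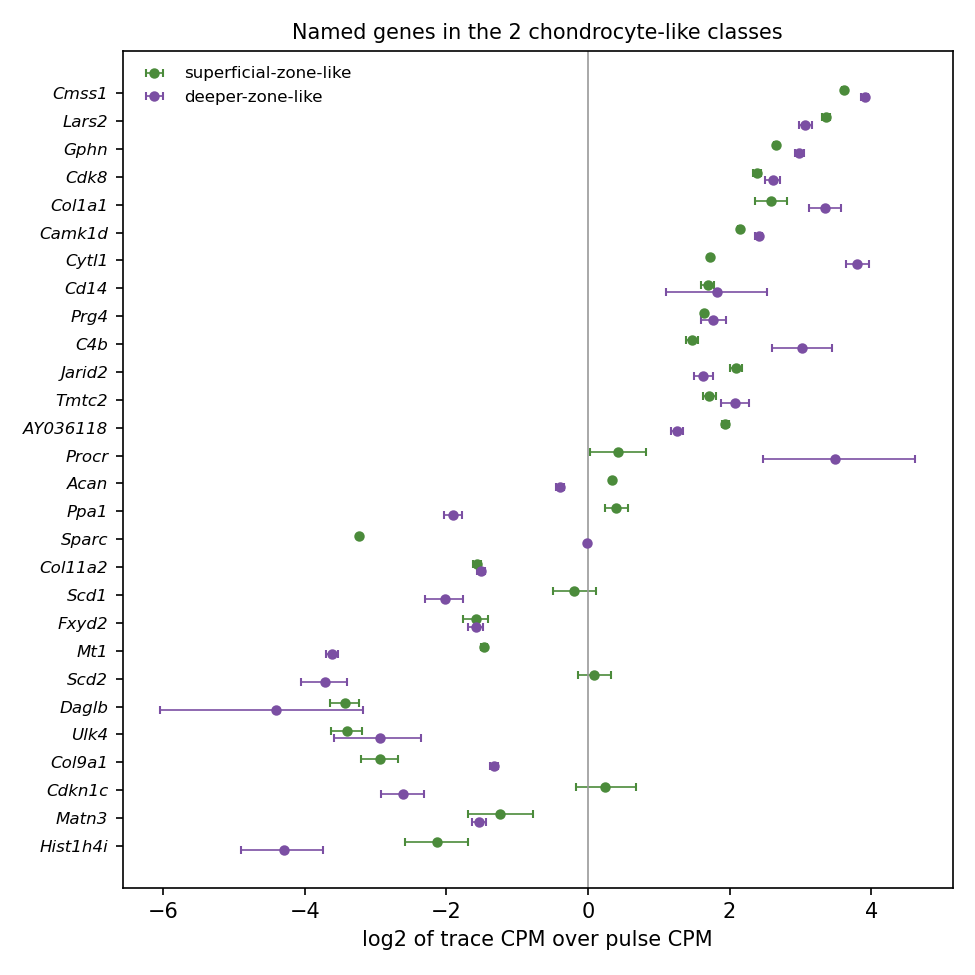
Log2 of trace CPM over pulse CPM (horizontal axis) for named genes (vertical axis) in superficial-zone-like and deeper-zone-like cells, with 1 library per group and bars for the exact 95% Poisson interval; Xist, Uty, Ddx3y and Msmp are left out. Sparc lay at -3.24 in superficial-zone-like and -0.01 in deeper-zone-like cells, and Prg4 lay at 1.64 in superficial-zone-like cells; its deeper-zone-like level was not told from free RNA.

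Zone markers also differed over the sum, although these lists named the classes and are not independent of them. Of 9 superficial-zone genes measured, 3 were at least 2-fold higher and none lower, with a median log2 ratio of 0.59, above 99.8% of 10000 random lists matched on size and expression. Clu was 2.87-fold and Cilp 2.54-fold higher, and Ecrg4 1.98-fold. Of 17 deeper-zone genes, 10 were lower and none higher, with a median of -1.57, below all random lists. Matn1 stood at 0.0341 of the pulse level and Epyc at 0.119. Within superficial-zone-like cells alone the medians were 0.43 and -0.52. The deeper-zone list also had medians of -2.68 in synovial lining-like cells and -2.13 in loose connective tissue fibroblast-like cells. Free cartilage RNA in the pulse library was therefore not excluded as part of the -0.52. The 4 hypertrophic genes measured had a median of -0.80, and Col10a1, the collagen gene of hypertrophic cartilage, stood at 0.625, with Mmp13 at 0.311. With the zones weighted alike their median turned to 0.17 and the log2 ratio of Mmp13 to 0.10. That of Col10a1 turned to 0.97 with at least 1000 genes per cell. Over both libraries, Col10a1 stood at 4697 and 3078 CPM in clusters 1 and 2 of the superficial-zone-like class. It stood at 347 and 1592 CPM in clusters 3 and 13, and at 358 CPM in deeper-zone-like cells.

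Matrix genes went both ways over the sum of both chondrocyte-like classes, which mixes the zones in different shares. Of 15 fibrillar and fibrous matrix genes, 1 (Col1a1) was at least 2-fold higher and 2 (Sparc, Lox) lower, with a median of 0.03. In superficial-zone-like cells 1 of 15 was higher and 2 lower (median 0.07). In deeper-zone-like cells 5 of 13 were higher and none lower, with a median of 0.56, at percentile 99.85 of random lists. The log2 ratio of Lox, -1.09, turned to 1.47 with at least 1000 genes per cell, 1.43 at Leiden resolution 1 and 2.84 with naming by fold over the mean. Fn1, the fibronectin gene, was 1.72-fold higher. Of 9 small leucine-rich proteoglycan genes, 2 were higher and 3 lower over the sum, with a median of 0.45, above 99.7% of random lists. Within the zones no measured member was at least 2-fold lower. In superficial-zone-like cells 2 of 8 were higher (median 0.39), and in deeper-zone-like cells 5 of 9 (median 1.05). The lower calls over the sum are therefore not read as a fall within a zone. Dcn, the decorin gene, was 2.53-fold higher and Ogn 2.90-fold, and Fmod, the fibromodulin gene, stood at 0.428. The ratio of Ogn turned slightly lower in trace with at least 1000 genes per cell. Of 9 matrix-degrading enzymes and inhibitors, 1 (Mmp13) was lower, with a median of 0.09. Of 10 ossification regulators, 4 were lower, with Runx2 at 0.395 and Pth1r at 0.323, and 1 was higher, Mgp, an inhibitor of calcification, at 2.45-fold. Their median was -0.94 over the sum, at percentile 0.05 of random lists, and 0.15 with the zones weighted alike, where Runx2 and Pth1r had log2 ratios of 0.17 and 0.15. It was -0.89 in superficial-zone-like cells, with 4 of 8 lower and 1 higher, and 0.69 in deeper-zone-like cells, with 4 of 12 higher and 1 lower, above all random lists.

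Of 13 BMP and TGF-beta genes, 2 were higher and 4 lower over the sum, with a median of -0.31. Id2 was 2.88-fold higher, Ltbp1 stood at 0.215 and Bmp2 at 0.478 of the pulse level. In superficial-zone-like cells 2 of 13 were higher and 3 lower (median -0.26). In deeper-zone-like cells 6 of 16 were higher and 2 lower (median 0.12). The log2 ratio of Bmp2 was 2.14 with naming by fold over the mean. Of 10 FGF, IGF and EGF genes, 1 (Igfbp5) was higher and 1 (Fgfr3) lower over the sum, with a median of -0.19. In superficial-zone-like cells none of 11 was higher and 1 lower (median -0.23). In deeper-zone-like cells 5 of 12 were higher and 2 lower, with a median of 0.69, at percentile 99.98 of random lists. The 5 Hedgehog genes (median -0.35) and the 11 mechanosensing and YAP/TAZ genes (median -0.14) had none past 2-fold over the sum. In deeper-zone-like cells 4 of 12 mechanosensing and YAP/TAZ genes were at least 2-fold higher and none lower, with a median of 0.16. In superficial-zone-like cells none of 11 passed 2-fold, with a median of -0.29. Only 3 Wnt genes were measured, with Lef1 at 0.345, Wif1 1.81-fold higher and a median of 0.58, which was -0.27 at a floor of 10 CPM. With the zones weighted alike the log2 ratio of Lef1 was 0.41. Notch genes had 2 members measured, both past 2-fold, Hes1 higher at 2.31-fold and Notch2 lower at 0.444, too few for a median. Of 7 progenitor-associated genes, Pdgfra was higher at 2.14-fold and none was lower over the sum, with a median of -0.26. That median turned positive with naming by fold over the mean. In superficial-zone-like cells none of 7 was at least 2-fold higher and 1 was lower (median -0.52). In deeper-zone-like cells 1 of 10 was higher and none lower (median 0.24).

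The 17 immediate early and dissociation response genes had a median of -0.48, with 5 at least 2-fold lower, among them Klf6 at 0.240 and Jun at 0.311. In superficial-zone-like cells alone 3 of the 17 were higher and 5 lower, and Fos was 5.21-fold higher (4.69 to 5.79). Fos was also a leading gene of cluster 13, with 25 pulse and 150 trace cells. How far its rise extends over the rest of the class is not shown. None of 10 heat shock genes passed 2-fold, and their median was 0.18. Hspa1a was 1.69-fold higher, but its log2 ratio was -1.54 without cluster 13. None of 16 glycolysis and hypoxia genes passed 2-fold over the sum, where their median was 0.22, but the zone medians had opposite signs. The median was 0.43 in superficial-zone-like cells, at percentile 99.98 of random lists, with none of 16 past 2-fold. In deeper-zone-like cells it was -0.72, at percentile 0.26, with 3 of 16 lower. Random lists were not matched on gene length, and the difference between the zones was not tested. None of 15 oxidative phosphorylation genes passed 2-fold over the sum, with a median of -0.05, which was 0.23 in superficial-zone-like and -0.54 in deeper-zone-like cells. Short genes as a whole split the same way. In the shortest of 10 equal length bins of protein-coding genes, the median was 0.29 in superficial-zone-like and -0.38 in deeper-zone-like cells. In the longest bin it was -0.50 and -0.33. Gene length was not tested for this list and stays open as a source of its split. The 8 inflammation and NF-kB genes had a median of 0.28 with 1 (Nfkbia, 2.16-fold) higher, and -0.12 within superficial-zone-like cells. The median of 0.28 turned negative when each library was clustered on its own. It also did so with the mean over cells of each cell's CPM and with the zones weighted alike. The 4 interferon response genes had a median of 0.56 and none past 2-fold. Of 12 antioxidant and lipid-handling genes, 5 were lower, with Mt2 at 0.228, and 1 was higher, Gpx3 at 2.54-fold, for a median of -0.51.

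Markers of other cell types in the chondrocyte-like cells were few. The 4 erythroid genes measured were all higher in trace with a median of 9.76, and Hbb-bs stood at 0.495 CPM in pulse and 282 CPM in trace. In loose connective tissue fibroblast-like cells the 4 erythroid genes measured were all lower in trace, with a median log2 ratio of -4.53. The 161 pulse cells of that class held 257 haemoglobin UMIs, and how these spread over the cells was not examined. In the chondrocyte-like cells the neutrophil gene S100a9 stood at 2.26 and 25.1 CPM. Synovial lining markers had 3 members measured, with Htra4 2.26-fold higher and a median of 0.38. Loose connective tissue markers had 2, Col15a1 (1.21-fold) and Smoc2 (0.979). Single members were measured over the sum for osteoblasts (Ibsp, 1.00, which hides the opposite ratios of the zones above), periosteal fibroblasts (Ogn, 2.90), tendon or ligament cells (Fmod, 0.428), mural cells (Cspg4, 0.431) and Schwann cells (Mbp, 0.587). None reached 20 CPM for marrow stromal, endothelial, skeletal muscle, macrophage or monocyte, lymphocyte and osteoclast lists.

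The Procr comparison asks whether the gene that drove the label was still read in the labelled cells. In superficial-zone-like cells Procr stood at 6.51 CPM (5.17 to 8.09) in pulse and 8.69 CPM (7.45 to 10.1) in trace, a ratio of 1.34 (1.02 to 1.76). The ratio of 1.90 over both classes rests partly on the deeper-zone-like trace cells, in which 34 Procr UMIs lay in 2 cells. In log2 that ratio was 0.93, and it was 0.48 for summed thinned cells and -0.05 when cluster 5 joined the superficial-zone-like class. With cells thinned to 2000 UMIs, 1.22% (0.893% to 1.62%) of pulse and 1.66% (1.29% to 2.11%) of trace chondrocyte-like cells had a Procr UMI. Unthinned shares were 1.71% and 3.11%, at median depths of 3065 and 4110 UMIs. Neutrophil-like trace cells, which should lack the gene, had it in 3.73% (1.22% to 8.49%) of cells thinned to 2000 UMIs. That level rests on 5 of 134 cells, and osteoblast-like trace cells had the gene in 0.976% (0.118% to 3.48%). The pulse library held 4 neutrophil-like cells, so its share was also set against trace cells. The chondrocyte-like shares did not exceed the neutrophil-like level, so background was not excluded.

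Procr was far higher in other classes. Mural-like cells had 2080 CPM in pulse and 1451 CPM in trace, loose connective tissue fibroblast-like cells 705 and 376 CPM, and synovial lining-like cells 487 and 319 CPM. Endothelial-like cells had 127 and 174 CPM, and cluster 5 had 123 and 59.0 CPM. Tdtomato, the reporter transcript, had 0.109 UMIs per superficial-zone-like cell in pulse (0.0991 to 0.120) and 0.297 in trace (0.282 to 0.314). In trace it was 0.612 per synovial lining-like cell and 0.383 per deeper-zone-like cell, and 0.0367 (0.0168 to 0.0697) per neutrophil-like cell. Osteoblast-like and lymphocyte-like trace cells had 0.0413 (0.0226 to 0.0693) and 0.0689 (0.0454 to 0.100), close to the neutrophil-like level. Thinned cells with a Tdtomato UMI were 6.19% of chondrocyte-like cells in pulse and 11.2% in trace, against 3.73% of neutrophil-like trace cells.

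**Figure D3:**
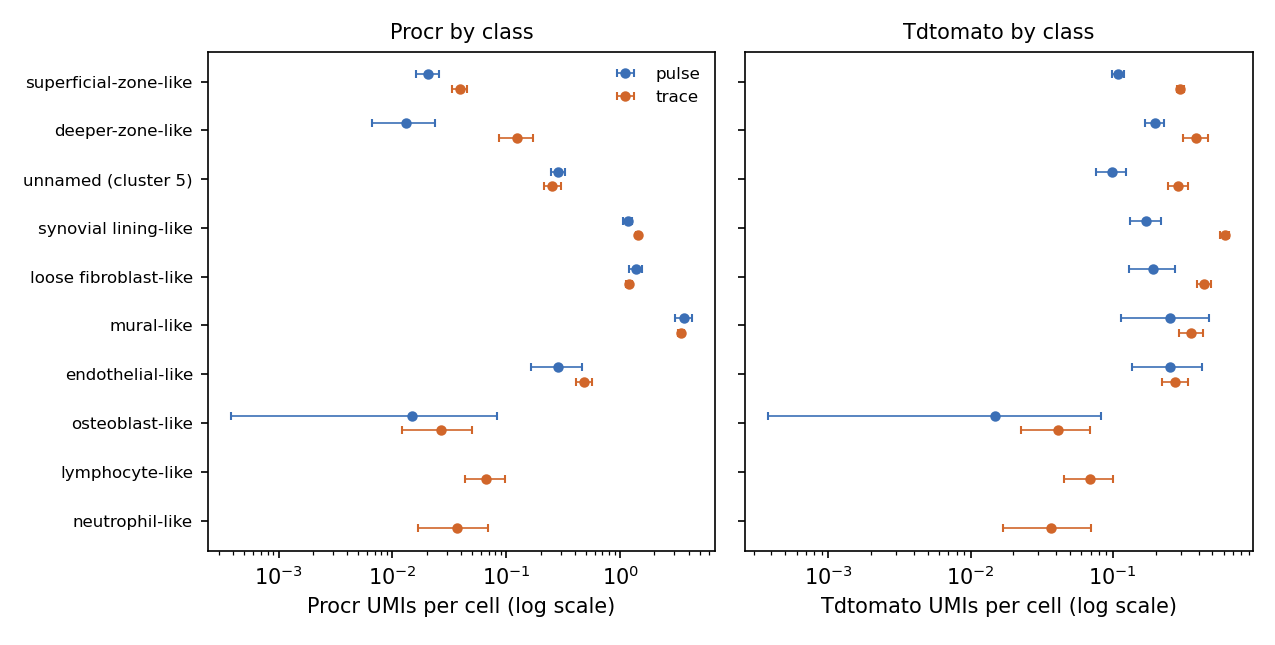
Procr and Tdtomato UMIs per cell (horizontal axes, log scale) by cell class (vertical axis) in the pulse and trace libraries, with 1 library each and bars for the exact 95% Poisson interval; classes with under 30 cells or no UMI in a library are left out. In trace, superficial-zone-like cells had 0.0390 Procr UMIs and 0.297 Tdtomato UMIs per cell, against 0.0367 of each in neutrophil-like cells.

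The cell cycle comparison asks how many labelled cells carried transcripts of dividing cells. Among chondrocyte-like cells thinned to 2000 UMIs, 23.7% (22.3% to 25.1%) in pulse and 10.7% (9.79% to 11.7%) in trace had 2 or more UMIs of S or G2/M genes. In superficial-zone-like cells the shares were 19.1% (17.7% to 20.5%) and 10.4% (9.48% to 11.5%), and in deeper-zone-like cells 43.7% (40.0% to 47.4%) and 15.8% (11.3% to 21.2%). They were 16.6% and 9.33% in synovial lining-like cells and 20.2% and 13.3% in cluster 5. Endothelial-like cells (21.7% and 25.3%) and osteoblast-like cells (3.85% and 13.7%) went the other way, on only 23 and 26 pulse cells. With 5 or more UMIs the shares were 0.554% (0.323% to 0.885%) and 0.105% (0.0287% to 0.270%) in superficial-zone-like cells, and 17.7% (14.9% to 20.7%) and 1.32% (0.272% to 3.80%) in deeper-zone-like cells. The proliferation genes Top2a and Mki67 stood at 0.0555 and 0.0824 of the pulse level over the class sums, and all 4 G2/M genes measured were lower, with a median of -2.86. The S phase genes had 4 members measured, 2 of them lower, and a median of -1.06. These sums mix the zones unequally, with 17.4% deeper-zone-like cells in pulse and 5.73% in trace. The mix of UMIs was more unequal still. Deeper-zone-like cells gave 5732952 of the 18175040 summed UMIs in pulse and 1581429 of 21835072 in trace. In deeper-zone-like cells all 12 G2/M and all 5 S genes measured were lower. In superficial-zone-like cells only 1 G2/M gene was measured, not past 2-fold, and 1 of 3 S genes was lower. Shares over both chondrocyte-like classes were 38.0% and 28.0% without thinning, and free RNA was left open as a source of low counts.

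Over all kept cells, 6637 genes reached 20 CPM, of which 234 were at least 2-fold higher in trace and 611 at least 2-fold lower. The higher genes included, after Xist at 2573-fold (880 to 12478), the neutrophil granule and calprotectin genes S100a8 (46.2-fold), Ngp (39.8-fold), S100a9 (37.0-fold) and Camp (26.8-fold). Neutrophil-like cells were 4 of the pulse and 245 of the trace cells. The lower genes opened with Uty and Ddx3y, followed by Matn3 at 0.0618 of the pulse level, Col9a1 at 0.0679 and Fxyd2 at 0.0805. Deeper-zone-like cells, which carried Matn3 and Col9a1, were 13.4% of pulse and 3.12% of trace. These ratios include the differing class shares, and scaling by the median ratio gave 335 higher and 408 lower.

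Positions are given on GRCm38 (mm10) with GENCODE M21, for the whole gene. Procr (ENSMUSG00000027611) lies on chromosome 2 from 155751117 to 155755471, Prg4 (ENSMUSG00000006014) on chromosome 1 from 150449412 to 150466165, and Acan (ENSMUSG00000030607) on chromosome 7 from 79053483 to 79115099. Sparc (ENSMUSG00000018593) lies on chromosome 11 from 55394500 to 55423183, Cytl1 (ENSMUSG00000062329) on chromosome 5 from 37735519 to 37739820, and Msmp (ENSMUSG00000078719) on chromosome 4 from 43583216 to 43584494. Ibsp (ENSMUSG00000029306) lies on chromosome 5 from 104299171 to 104311469, Matn3 (ENSMUSG00000020583) on chromosome 12 from 8947929 to 8972028, and Col9a1 (ENSMUSG00000026147) on chromosome 1 from 24177610 to 24252684. Each is annotated as protein-coding.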

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

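All of the tests in this part were chosen after the results they bear on were seen. Ibsp, the bone sialoprotein gene, stood out because the chondrocyte-like classes went opposite ways. Its log2 ratio of trace over pulse was -1.59 in superficial-zone-like cells (327 CPM in pulse and 109 CPM in trace) and 4.91 in deeper-zone-like cells (67.0 and 2010 CPM), a difference of -6.50. Of the other 3 osteoblast markers measured in deeper-zone-like cells, only Bglap was at least 2-fold higher (3.70-fold), and Col1a1 stood at 39.1 CPM in pulse and 396 CPM in trace. This difference between the zones was not tested, since each class had 1 library per group. Haemoglobin genes stood out in data that no comparison used. They made up 9.18% of UMIs in the 1176 trace barcodes left out by the cell filter and none of those in the 330 pulse barcodes left out, although the sort excluded Ter119-positive cells.

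In 5 cell sets (superficial-zone-like, deeper-zone-like, synovial lining-like, loose connective tissue-like cells and cluster 5), more genes were at least 2-fold lower in trace than higher, with 559 against 149 in superficial-zone-like cells. Non-coding genes alone are argued against, since protein-coding genes kept a ratio of lower over higher genes of 3.11 or more. The 6 rRNA-associated genes took 9.15% of trace and 0.976% of pulse UMIs. Without them, 148 genes were higher and 515 lower over both chondrocyte-like classes, against 107 and 630 with them. The surplus thus shrank there but stayed. Gene length as the whole cause is argued against in deeper-zone-like cells, where the median log2 ratio of the longest of 10 equal bins of protein-coding genes lay 0.042 above that of the shortest (-0.063 to 0.12 over 1000 resamplings of genes, which are not independent), but stays open in superficial-zone-like cells (-0.79), cluster 5 (-0.65), loose connective tissue-like (-0.50) and synovial lining-like cells (-0.27). A single scaling factor cannot be told apart, since scaling by the median ratio of each set, which itself centres the genes, took the ratio of lower over higher genes from between 3.75 and 6.33 to between 1.02 and 1.39. Antisense genes lay below protein-coding genes by log2 differences of -1.04 or beyond in every set, which is consistent with RNA of other kinds or strands being counted in unequal shares, but they were only 80 of the 630 lower genes over both chondrocyte-like classes, and intron counting, RNA quality, age and sex stay open as untested explanations.

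In superficial-zone-like cells, Prg4 was higher and Sparc lower in trace, by 94.99 more Prg4 and 108 fewer Sparc UMIs per cell. Free Prg4 RNA is argued against, since neutrophil-like and lymphocyte-like trace cells held at most 3.72 Prg4 UMIs per cell. Free Sparc RNA was set against other classes. It is argued against by endothelial-like pulse cells, the lowest named pulse class of 50 or more cells, with at most 6.09 Sparc UMIs per cell. Neutrophil-like and lymphocyte-like pulse cells held more, at 49.75 (43.1 to 57.2) and 26.0 (21.2 to 31.5), but were only 4 cells each. The sex of the pooled mice cannot be told apart from the groups, since only 0.0483% of pulse cells had an Xist UMI, and age and chase time went with it. Gene length bias is argued against, since other protein-coding genes as long as Prg4 had a median log2 ratio only 0.20 above those as long as Sparc, against the 4.88 between the 2 genes. A difference over the chase may therefore remain, but so may a difference between the zones or cell states that the clusters of this class sample.

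Superficial-zone-like trace cells held few Procr UMIs beside their Tdtomato UMIs. Poor capture of Procr is argued against by 1451 CPM in mural-like trace cells, and free Tdtomato RNA by 0.297 Tdtomato UMIs per superficial-zone-like cell, above the bound of 0.100 from neutrophil-like, lymphocyte-like and osteoblast-like trace cells. Free Procr RNA stays open as a source of the Procr UMIs, since the 0.0390 per cell did not exceed the bound of 0.0972 from the same 3 classes. That bound came from the lymphocyte-like cluster, whose leading genes were mixed. The neutrophil-like and osteoblast-like bounds, 0.0697 and 0.0504, were not exceeded either. Low expression below this depth, loss of Procr after labelling and labelling of cells other than current Procr-expressing ones may each apply, and none was tested.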

How the results depend on the processing

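The alternatives on Scrublet's own threshold, the 6 rRNA-associated genes, the weighting of zones, the heat shock cluster and the naming of clusters were chosen after the data were seen, and the others were planned. Prg4 stayed higher in trace under every alternative run, with log2 ratios from 1.64 to 6.22 and 2.08 as reported. Lower genes outnumbered higher genes in chondrocyte-like cells under every one. The 6.22 came from naming by fold over the mean, which left 3.13% of pulse cells superficial-zone-like. The deeper-zone-like share of pulse stayed at 12.5% or more under every alternative. That setting therefore compares unlike zone mixes and adds nothing on Prg4. The deeper-zone-like share stayed higher in pulse, and the share of cells in cycle stayed higher in pulse. Acan and Procr each reversed under 1 alternative, and the Procr ratio rests on few UMIs. With 3000 variable genes, and with every gene allowed among the leading genes, no sign reversed and no class share, gene count, cycle share or Procr, Prg4 or Acan ratio moved beyond its counting interval (for gene counts, 1.5 times). Values that did so under the other alternatives follow. The superficial-zone-like share was higher in pulse as reported and lower in pulse than in trace with at least 1000 genes per cell, at Leiden resolution 1 and with naming by fold over the mean of the other clusters. For this and all values below the cause was not tested, apart from the zone mix given above for naming by fold over the mean. By construction, a higher or lower floor tests fewer or more genes and thinning lowers UMIs per cell. The planned weighting of clusters alike was not run. No paired analysis was possible because each group had 1 library and no cell is assigned to a mouse. Depth limits genes near the floor, Procr in chondrocyte-like cells and the pulse classes of few cells.

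With at least 1000 genes per cell, the superficial-zone-like share was 36.1% (pulse) and 40.2% (trace), the deeper-zone-like share was 14.8% (pulse) and genes past 2-fold in chondrocyte-like cells numbered 189 higher. There, log2 ratios moved to Procr 0.24, Prg4 2.36 and Acan 0.83 and cells in cycle were 29.0% (pulse) and 9.59% (trace). Log2 ratios reversed to Col10a1 0.97, Smoc2 1.44, Has1 -0.25, Ogn -0.073, Lox 1.47, Axl 0.29 and Sox6 0.030. With no cell filter, the superficial-zone-like share was 61.5% (pulse) and 47.9% (trace) and log2 ratios moved to Prg4 2.06. At Leiden resolution 1, the superficial-zone-like share was 31.0% (pulse), genes past 2-fold in chondrocyte-like cells numbered 169 higher and log2 ratios moved to Prg4 2.24 and Acan 0.63. There, cells in cycle were 30.7% (pulse). Log2 ratios reversed to Col10a1 1.08, Smoc2 1.18, Lox 1.43 and Axl 0.44. With each library clustered on its own, the superficial-zone-like share was 46.7% (pulse) and 26.8% (trace), log2 ratios moved to Prg4 1.84 and cells with a Procr UMI were 1.72% (pulse). There, cells in cycle were 27.7% (pulse) and 13.6% (trace). List medians reversed to Hedgehog 0.026 and inflammation -0.88 and log2 ratios reversed to Acan -0.25, Alpl 0.037, Spp1 -0.49, Hbegf -0.053, Timp1 -0.49, Ltbp2 -1.55, Hhip 0.026, Cxcl2 -1.62, Lcn2 -1.37 and Ifi27 0.024. With predicted doublets kept, the superficial-zone-like share was 49.8% (trace) and log2 ratios moved to Procr 0.49. With at most 5% mitochondrial UMIs, the deeper-zone-like share was 12.5% (pulse) and log2 ratios moved to Prg4 2.06. With scaling by the median ratio, genes past 2-fold in chondrocyte-like cells numbered 218 higher and 418 lower and log2 ratios moved to Prg4 2.33 and Acan 0.57. Sign reversed for Smoc2 0.22. At a floor of 100 CPM, genes past 2-fold in chondrocyte-like cells numbered 57 higher and 158 lower and genes past 2-fold over all kept cells numbered 79 higher and 186 lower. At a floor of 10 CPM, genes past 2-fold in chondrocyte-like cells numbered 1089 lower and genes past 2-fold over all kept cells numbered 383 higher and 945 lower. List medians reversed to Wnt -0.27. With the mean over cells of each cell's CPM, log2 ratios moved to Procr 0.53, Prg4 1.70 and Acan 0.18. List medians reversed to inflammation -0.031 and log2 ratios reversed to Hbegf -0.15. With cells thinned to 2000 UMIs before summing, log2 ratios moved to Procr 0.48, Prg4 1.79 and Acan 0.26. Sign reversed for Hbegf -0.11. With a pseudocount of 5 CPM, log2 ratios moved to Procr 0.54. Without mitochondrial, ribosomal protein and haemoglobin genes, log2 ratios moved to Prg4 2.10 and Acan 0.34. With cells thinned to 1000 UMIs, cells with a Procr UMI were 0.512% (pulse) and 0.886% (trace) and cells in cycle were 9.13% (pulse) and 3.22% (trace). Without thinning, cells with a Procr UMI were 1.71% (pulse) and 3.11% (trace) and cells in cycle were 38.0% (pulse) and 28.0% (trace). With 3 or more cycle UMIs, cells in cycle were 10.8% (pulse) and 2.73% (trace).

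Of the alternatives added after the data were seen, the values were these. With naming by fold over the mean of the other clusters, with or without every gene allowed, the superficial-zone-like share was 3.13% (pulse), genes past 2-fold in chondrocyte-like cells numbered 517 higher and 1389 lower and log2 ratios moved to Procr 2.06, Prg4 6.22 and Acan 0.39. There, cells with a Procr UMI were 0.135% (pulse) and cells in cycle were 42.3% (pulse). List medians reversed to Wnt -0.00343, progenitor-associated 0.27 and antioxidant 0.16 and log2 ratios reversed to Col10a1 1.68, Smoc2 2.32, Lox 2.84, Timp1 -0.095, Bmp2 2.14, Axl 1.32, Sox6 0.30, Sox5 0.26, Tnfaip6 0.63, H2-K1 -0.13 and Nqo1 0.00854. With only classes of 3 raised markers as candidates, the superficial-zone-like share was 75.1% (pulse) and 57.3% (trace), log2 ratios moved to Prg4 2.02 and Acan 0.28 and cells with a Procr UMI were 2.56% (pulse) and 2.29% (trace). Sign reversed for Procr -0.049 and Hbegf -0.028. With Scrublet's own threshold, log2 ratios moved to Procr 0.38. Without the 6 rRNA-associated genes, log2 ratios moved to Prg4 2.19 and Acan 0.43. Sign reversed for Smoc2 0.086. With the zones weighted alike, log2 ratios moved to Prg4 1.64 and Acan 0.27. List medians reversed to hypertrophic 0.17, inflammation -0.10 and ossification regulators 0.15 and log2 ratios reversed to Mmp13 0.10, Alpl 0.57, Hbegf -0.11, Lef1 0.41, Pth1r 0.15, Runx2 0.17 and Runx3 0.57. Without the heat shock cluster, log2 ratios moved to Prg4 2.05 and Acan 0.34. Sign reversed for Hspa1a -1.54 and Dnajb1 -1.04.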

Other observations

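The genes in this part were picked by the size rule for named genes, applied to other cell classes after their values were seen, and no explanation was tested for them. In deeper-zone-like cells, the serine protease inhibitor genes Serpina1a, Serpina1d and Serpina1b were 84.9-fold (59.6 to 125), 42.0-fold (30.0 to 60.5) and 22.2-fold (17.8 to 28.0) higher in trace. Chad, the chondroadherin gene, was 6.10-fold higher, at 477 CPM in pulse and 2908 CPM in trace. The histone genes Hist1h2ae and Hist1h2ap stood at 0.0152 and 0.0524 of the pulse level. Gpnmb, a membrane glycoprotein gene, stood at 235 CPM in pulse and 5.06 CPM in trace.

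In synovial lining-like cells, Rspo2, which encodes a potentiator of Wnt signalling, was 3.70-fold higher in trace (2.84 to 4.90), and Socs3, a feedback inhibitor of cytokine signalling, was 3.51-fold higher (2.55 to 4.95). The transcription factor gene Ets2 and the heat shock gene Hspa1b stood at 0.179 and 0.232 of the pulse level there. Of 9 inflammation and NF-kB genes measured in these cells, 6 were at least 2-fold lower and none higher, with a median log2 ratio of -1.17, at percentile 0.01 of random lists. Lists that respond to handling were lower there too, with medians of -0.65 for 17 immediate early and dissociation response genes (5 lower, 1 higher) and -0.73 for 10 heat shock genes (3 lower). In loose connective tissue fibroblast-like cells, Myoc was 7.50-fold higher (4.66 to 12.9). Il1rl1, the interleukin-33 receptor gene, had 3.17 CPM in pulse and 140 CPM in trace there. Its ratio rested on so few pulse UMIs that its interval ran from 7.86 to 1747. In cluster 5, Mmp3, a matrix-degrading enzyme gene, was 4.84-fold higher, Wif1 2.91-fold and Fmod 2.59-fold, while Sox9 stood at 0.260 and Egr1 at 0.185 of the pulse level. Across the 5 cell sets and the 4765 genes measured in all of them, 16 were at least 2-fold higher in each and 62, of which 14 were antisense genes, at least 2-fold lower in each. All 5 sets came from the same 2 libraries, so any difference between the libraries as a whole adds to this agreement. The 16 included Xist, Gm42418, Cmss1, Gphn, Lars2, Camk1d, Cdk8 and Jarid2, and the 62 included Actb, Klf6, Rela, Ulk4 and Daglb.

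Haemoglobin UMIs per cell differed between trace classes, at 8.37 per lymphocyte-like cell, 8.35 per osteoblast-like cell, 3.17 per mural-like cell, 2.34 per superficial-zone-like cell and 0.113 per deeper-zone-like cell. Loose connective tissue fibroblast-like cells went the other way, with 1.60 per cell in pulse (1.41 to 1.80) and 0.141 in trace (0.115 to 0.171). The pulse value came from 257 UMIs in 161 cells, and no other pulse class held more than 11. How these UMIs spread over the cells was not examined. A few cells could hold most of them, which the interval does not cover.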
